A study of Homo sapiens with 6 samples.

How the data were processed

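RNA was measured in human pulmonary arterial smooth muscle cells, primary cells from 2 healthy donors, in 3 groups of 2 libraries each. Cells at passage 2 were treated for 24 h with vehicle (20 µL PBS and 10 µL DMSO), with doxorubicin at 0.5 µg/ml or with Nutlin-3 at 10 µM. Total RNA was column-purified and sequenced from strand-specific libraries, per the labels. The replicate number names the donor, so libraries with the same number form a pair across groups.

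The authors deposited a table of raw counts per gene, with 35858 genes, not scaled for depth or length. The authors also deposited tables of log2 fold changes with p values and false discovery rates, 1 for each treatment against control, which list only genes with a false discovery rate under 0.05. In these tables, positive log2 values mean higher in treated libraries, which was checked against the counts. The processing notes name BWA, DESeq2 and the builds hg38 and GRCh38 without versions, and the count table bears the name of SeqMonk. The annotation release and the counting of introns, of strand and of reads with more than 1 position were not given in the sources used here. BWA has no model of splicing, so reads across exon junctions can be clipped or lost, which lowers counts of genes with short exons. Reads of near-identical genes, such as histone genes, ribosomal protein genes and their pseudogenes, can be placed on the wrong copy. Of the genes kept, 96.2% matched GENCODE release 29 by symbol and position, and 96.3% of those had the same start and end.

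The columns named as controls were taken as the vehicle libraries. XIST, TSIX and genes of chromosome Y (135 in all) were left out of every test and table, which left 35723. Counts were 0 in all 6 libraries for 12483 genes, among them 13 mitochondrial genes and MYH11. In 27 cases the symbol had been turned into a date, and 92 entries shared a symbol with another. Library totals are given with the results, and a count of 0 over a group was given a floor of 3 counts.

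The calls came from edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM scaling, the filterByExpr filter and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The filter left 16199 genes. All 6 libraries were fitted together on group means with 3 residual degrees of freedom, a prior of 2.78 degrees of freedom and a common dispersion of 0.0555. Fold changes of edgeR used a prior count of 0.125. With n = 2 per group, p measures the spread between the libraries of 2 donors. Levels are CPM, edgeR's counts scaled to library size, after TMM scaling, as mean and SD of the 2 libraries. A check of the pairing correlated the deviations of the replicates from their group mean between groups, across genes, and gave 0.560 for vehicle and doxorubicin, 0.723 for vehicle and Nutlin-3 and 0.525 for doxorubicin and Nutlin-3. A fit with the replicate number as a block was run as an alternative, with 2 residual degrees of freedom and a common dispersion of 0.0122. The main fit did not use the pairing, so donor differences stayed in its error. Genes and lists not called by the main fit may therefore pass with the block.

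Comparisons were doxorubicin against vehicle, Nutlin-3 against vehicle and doxorubicin against Nutlin-3, plus the overlap of the first 2. The comparisons, alternatives, rule for named genes and 22 gene lists were set before the data were examined. The lists cover p53 targets, cell cycle, repair, histones, signalling, matrix, contraction, metabolism and stress, and markers of endothelial, epithelial, leukocyte and fibroblast cells. The list of 13 mitochondrially encoded proteins had no measured member, which left 21. Lists were tested with camera at an inter-gene correlation of 0.01 and adjusted over the 21 lists of a comparison, with an estimated correlation and fry as alternatives.

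CDKN1A and MDM2 were among the genes named whatever their test. The rule also took the 4 largest rises and 4 largest falls of each treatment against vehicle. The latter had to have a mean log2 CPM of at least 2 over all 6 libraries, a symbol that is not a clone or LOC name, an adjusted p under 0.05 and both treated libraries on the same side of both vehicle libraries. From each list with at least 3 called members the 2 with the smallest adjusted p were added. Between treatments the rule took the 5 largest differences each way and up to 4 genes called in opposite directions against vehicle. Fold changes and calls with shared vehicle libraries were simulated 100 times from the fitted levels and dispersion, without effects, and without the donor block.

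Alternatives were RLE scaling, library totals alone, DESeq2 1.42.0, limma-voom, no filter on low counts, the replicate block, only the 4 libraries compared, at least a 2-fold change, and leaving out each library in turn. Where a library was left out, the lone sample was assumed to vary like the other groups. That group then held 1 donor and the others 2, so shifts of these fits can hold donor differences. The filter was also rerun for each set of libraries, so the measured members of a list could differ. Splits of the samples were not counted, since groups hold 2 libraries. The test was also run on 1 set of simulated counts with known changes. It found 26.2%, 83.6% and 92.6% of 2-, 4- and 8-fold changes with doxorubicin, 18.8%, 87.9% and 89.2% with Nutlin-3, and 33.6%, 88.7% and 96.2% between treatments. False calls were 4.23%, 11.0% and 7.91% of calls, above the nominal 5% in the latter 2. With the replicate block it found 91.3%, 89.2% and 91.8% of 2-fold changes, with 11.8%, 12.3% and 8.71% false calls. That run drew from the smaller dispersion of the blocked fit, and neither run held a donor effect, so the higher recovery does not measure blocking. Without the block, 65, 67 and 68 of 14684 genes were changed 2-, 4- and 8-fold with doxorubicin. That is far fewer than were called in the data, so these rates may not hold there. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.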

Results

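Pulmonary arterial smooth muscle cells, the contractile cells of the wall of lung arteries, were grown from 2 healthy donors and treated at passage 2 for 24 h. Each donor gave 1 library treated with vehicle, 1 treated with doxorubicin at 0.5 µg/ml and 1 treated with Nutlin-3 at 10 µM, so that every group held 2 libraries (n = 2) and the replicate number marked the donor. Doxorubicin is an anthracycline that poisons topoisomerase II and breaks DNA. Nutlin-3 is a small molecule that keeps the ubiquitin ligase MDM2 from binding p53, so that p53 accumulates without DNA damage. The study asked which transcripts change under genotoxic stress and which under direct activation of p53. RNA was sequenced from strand-specific libraries and delivered as raw counts per gene. The libraries held 29147711 and 26437097 counts for vehicle, 23993050 and 22659803 for doxorubicin, and 24681220 and 25401243 for Nutlin-3, in the order of replicates 1 and 2. Genes with at least 10 counts numbered 14855 and 14556 in vehicle, 16178 and 15608 with doxorubicin, and 14854 and 14688 with Nutlin-3. Log2 expression of the 2 donors correlated across the 16199 genes tested with r = 0.980 in vehicle, 0.974 with doxorubicin and 0.979 with Nutlin-3. Genes are not independent replicates. The first principal component carried 70.9% of the variance and set the doxorubicin libraries, at 140.7 and 107.9, apart from the other 4, which lay between -79.5 and -45.7.

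Doxorubicin changed the relative level of 52.8% of the tested transcripts, and the p53 pathway was among the transcripts that rose. TMM scaling takes most genes as unchanged and left a median log2 fold change of 0.0042, so a shift common to all genes would not show. Of 16199 genes tested, 4540 were higher and 4020 were lower than in vehicle. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339, GRCh38), rose 4.04-fold, from 462 ± 49.8 to 1867 ± 62.8 CPM (counts scaled to library size, mean ± SD, n = 2; log2 fold change 2.01, SE 0.18, adjusted p = 0.000916). MDM2, itself a p53 target (chromosome 12, 68808176 to 68850686), rose 2.37-fold, from 174 ± 2.32 to 413 ± 48.8 CPM (log2 fold change 1.25, SE 0.21, adjusted p = 0.00559). In both genes both doxorubicin libraries lay above both vehicle libraries.

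Of 123 measured direct targets of p53, 115 rose and 3 fell, and 116 and 3 did so adjusted over the list alone. The 3 that fell were DDIT4, PGPEP1 and TM7SF3. The median log2 fold change was 2.38 (camera adjusted p = 2.49e-57, adjusted p = 0.133 with an estimated correlation). FDXR, a mitochondrial ferredoxin reductase, rose 21.0-fold to 314 ± 11.1 CPM, and TNFRSF10C, a decoy receptor for the death ligand TRAIL, rose 111-fold to 248 ± 32.2 CPM. Among 17 p53 targets that act in apoptosis, 13 rose and none was called lower (14 rose adjusted over the list alone), with a median of 2.45 (camera adjusted p = 5.67e-15, adjusted p = 0.0663 with an estimated correlation). TNFRSF10C belongs to both lists, and TP53I3, a quinone oxidoreductase, rose 17.3-fold to 683 ± 25.9 CPM (log2 fold change 4.11, SE 0.14, adjusted p = 0.000191).

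Genes of mitosis fell. Of 66 measured genes of G2/M and mitosis, 43 fell and 1 rose, the same numbers adjusted over the list alone (55 fell and 3 rose with a replicate block for the donors), with a median log2 fold change of -1.54 (camera adjusted p = 2.91e-09, adjusted p = 0.889 with an estimated correlation and 0.118 with fry). Without vehicle replicate 1 that median was -0.99, and the list still passed. The 1 that rose was PTTG1. PLK1, a mitotic kinase, fell to 0.0725 of its vehicle level, from 73.4 ± 34.3 to 5.32 ± 0.303 CPM, and ECT2, which drives cytokinesis, fell to 0.187 of it, from 66.4 ± 17.6 to 12.4 ± 0.205 CPM. Homologous recombination and Fanconi repair genes fell in 11 of 26 cases, with none called higher, also adjusted over the list alone, and 18 fell and 1 rose with the donors as a replicate block. Their median was -0.98 (camera adjusted p = 0.0164, adjusted p = 0.907 with an estimated correlation and 0.187 with fry). Without vehicle replicate 1 that median was -0.45 and the adjusted p 0.0963, and without doxorubicin replicate 2 they were -0.68 and 0.0864. UBE2T, a ubiquitin-conjugating enzyme of the Fanconi pathway, fell to 0.177 of vehicle and BRCA1 to 0.330. The 48 genes of G1/S and DNA replication went both ways, with 3 higher and 11 lower over all genes and over the list alone (10 and 15 with the replicate block). Their median of -0.19 did not pass (camera adjusted p = 0.305). Without vehicle replicate 2 the list passed (median -0.58, adjusted p = 0.0116), and without vehicle replicate 1 and doxorubicin replicate 2 its medians were 0.29 and 0.044. Those higher were GINS4, LIG1 and TYMS. GINS4, a subunit of the replicative helicase complex, rose 9.19-fold, while MCM3, another subunit, fell to 0.208 of vehicle.

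Replication-dependent histone transcripts, which encode the histones made for new chromatin, had the highest median of the 21 lists tested. Of 34 measured histone genes, 30 rose and none was called lower, the same adjusted over the list alone, with a median log2 fold change of 4.26, or 3.91 with 6 members near 0 counts set to their bounds (camera adjusted p = 6.94e-14, adjusted p = 0.669 with an estimated correlation). HIST1H2AE rose 87.2-fold to 35.0 ± 8.92 CPM and HIST1H2AG rose 24.2-fold. Of the 64 listed, 34 passed the filter, and 15 of these had 1 CPM or more in vehicle. Members low in vehicle could pass the filter through the treated libraries, which favours rises. With 1 library left out the median ranged from 3.84 to 4.06, under 4.26 throughout. The filter was rerun for each of those fits, so the measured members could differ. Histone genes are near-identical copies, so the value of a single copy is uncertain. Summed over all 64 listed histone genes, the libraries held 80.5 and 127.1 CPM in vehicle, 802.1 and 1249.7 CPM with doxorubicin, and 198.8 and 329.8 CPM with Nutlin-3.

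The largest rises by the naming rule were in genes with almost no reads in vehicle. DSC3, a desmosomal cadherin (chromosome 18, 30990008 to 31042815), had 0 counts in vehicle and 97.0 ± 33.6 CPM with doxorubicin, at least 1910.3-fold higher when vehicle is set to 3 counts over the group. By the same floor CRTAC1, a cartilage matrix protein (chromosome 10, 97865000 to 98030828), was at least 1598-fold higher at 79.9 ± 56.6 CPM, and NOTO, a notochord homeobox gene (chromosome 2, 73202258 to 73212513), at least 1026-fold higher at 51.8 ± 25.5 CPM. POU3F1, a POU-domain transcription factor (chromosome 1, 38044611 to 38046794), went from 1 count over the vehicle group to 239 ± 91.8 CPM, a ratio of 14142 with an exact 95% counting interval of 2538 to 558609. Adjusted p was 0.000759, 0.00153, 0.00203 and 0.000272 in that order. The largest falls were in GBP2, an interferon-inducible GTPase (chromosome 1, 89106132 to 89150456), KCNAB1, a potassium channel subunit (chromosome 3, 156037701 to 156539138), PSRC1, a spindle-associated protein (chromosome 1, 109279556 to 109283186), and ENPP4, an ectonucleotidase (chromosome 6, 46129993 to 46146699). GBP2 fell to 0.0191 of vehicle (20.9 ± 14.8 to 0.394 ± 0.00615 CPM), KCNAB1 to 0.0283 (55.6 ± 54.3 to 1.57 ± 0.152 CPM), PSRC1 to 0.0300 (15.3 ± 7.90 to 0.455 ± 0.0177 CPM) and ENPP4 to 0.0393 (10.4 ± 8.51 to 0.395 ± 0.433 CPM), with adjusted p of 0.00357, 0.0185, 0.00143 and 0.0203. The calls of KCNAB1 and ENPP4 were lost without vehicle replicate 1 (log2 fold changes -3.47 and -3.45) and without either doxorubicin library (-5.22 and -6.79 without replicate 1, -5.04 and -3.88 without replicate 2). They were also lost with limma-voom (adjusted p = 0.103 and 0.0776). In vehicle the 2 donors stood at 93.9 and 17.2 CPM for KCNAB1 and 16.5 and 4.42 CPM for ENPP4, a difference that the main fit left in its error. With the replicate block edgeR's adjusted p was 0.00029 and 3.62e-05.

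Single genes of contraction, matrix and growth factor signalling changed with doxorubicin, while none of these lists passed its test. Contractile genes were higher in 9 and lower in 5 of 25 cases (median 0.083, camera adjusted p = 0.632). SMTN, which encodes smoothelin, rose 5.59-fold to 389 ± 43.8 CPM, and ACTA2, smooth muscle alpha-actin, rose 3.56-fold to 156 ± 0.0137 CPM. MYH11, the smooth muscle myosin heavy chain, was listed at 0 in all 6 libraries. Of 47 collagen and matrix genes 3 rose and 3 fell (1 and 1 adjusted over the list alone, 14 and 17 with the replicate block; median -0.075, camera adjusted p = 0.693). Those higher were COL12A1, FBN2 and NID2, and those lower FBLN2, LAMB1 and THBS1. COL12A1 rose 2.04-fold and THBS1, the matrix glycoprotein thrombospondin-1, fell to 0.181 of vehicle. In the BMP and TGF-beta pathway 9 rose and 15 fell of 39 (median -0.35, camera adjusted p = 0.190). ENG, the co-receptor endoglin, fell to 0.264 of vehicle, from 633 ± 4.22 to 167 ± 25.7 CPM. Among 17 risk genes of pulmonary arterial hypertension 4 rose and 8 fell (median -0.54, camera adjusted p = 0.230). Those higher were CAV1, TBX4, EIF2AK4 and GGCX. ENG is one of those that fell, and ATP13A3, a polyamine transporter, fell to 0.237 of vehicle, from 1501 ± 171 to 356 ± 67.9 CPM. The contractile median turned to -0.011 without vehicle replicate 1, and the matrix median to 0.41 without vehicle replicate 2 and 0.24 without doxorubicin replicate 1. With 1 library left out the medians ranged from -0.011 to 0.53 for contractile, -0.39 to 0.41 for matrix, -0.35 to -0.16 for BMP and TGF-beta and -0.94 to -0.54 for hypertension risk genes.

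Stress, inflammatory and metabolic lists were mixed as well. Interferon response genes rose in 14 and fell in 7 of 37 cases (15 and 7 adjusted over the list alone; median 0.84, camera adjusted p = 0.266), with ISG20, an exonuclease, up 15.9-fold and TRIM22, which is also on the p53 list, up 3.58-fold. Of 33 NF-kB and secreted inflammatory factors 9 rose and 6 fell (median -0.19, camera adjusted p = 0.989). LIF, a cytokine also on the p53 list, rose 7.55-fold to 464 ± 22.4 CPM, and IL6 fell to 0.0937 of vehicle, from 186 ± 6.87 to 17.4 ± 7.17 CPM. Of 30 sterol synthesis genes 7 rose and 12 fell (13 lower adjusted over the list alone; median -0.50, camera adjusted p = 0.190). Without vehicle replicate 1 that list passed (median -0.62, adjusted p = 0.0263). SQLE, which makes squalene epoxide, fell to 0.238 of vehicle and TM7SF2, a sterol reductase, rose 4.37-fold. In the integrated stress response 10 rose and 8 fell of 28 (median -0.26, camera adjusted p = 0.989), with ATF3, a stress-induced transcription factor, up 125-fold and VLDLR, a lipoprotein receptor, down to 0.316. NRF2 target genes rose in 6 and fell in 7 of 23 cases (median -0.16, camera adjusted p = 0.635), AKR1B10 rising 17.9-fold and GCLC 2.71-fold. Immediate early genes rose in 15 and fell in 3 of 26 cases (4 lower adjusted over the list alone, 6 lower with the replicate block), with a median of 0.79 (camera adjusted p = 0.0389, adjusted p = 0.889 with an estimated correlation). That list no longer passed without vehicle replicate 1 (median 0.67, adjusted p = 0.067), vehicle replicate 2 (0.75, 0.0575) or doxorubicin replicate 1 (0.71, 0.07). On all libraries the immediate early list also lost its call with limma-voom (adjusted p = 0.0591), with no filter on low counts (0.0681) and with fry (0.0509). The 3 that fell were KLF2, ZFP36 and CYR61. BTG2, also a p53 target, rose 24.0-fold and DUSP5, a MAP kinase phosphatase, 22.2-fold. Ribosomal protein genes fell in 26 and rose in 5 of 74 cases (25 and 4 adjusted over the list alone; median -0.27, camera adjusted p = 0.0278, adjusted p = 0.889 with an estimated correlation). Those that rose were RPS27, RPL9, RPS24, RPL23A and RPS19. RPL3 fell to 0.443 of vehicle and RPL9 rose 2.59-fold, with pseudogene copies of both left uncertain. The NF-kB median turned to 0.31 and the NRF2 median to 0.073 without vehicle replicate 1, and without doxorubicin replicate 2 the NF-kB and stress response medians turned to 0.044 and 0.052. Over all libraries left out in turn the medians ranged from 0.22 to 1.37 for interferon, -0.34 to 0.31 for NF-kB, -0.54 to 0.052 for stress response and -0.33 to 0.073 for NRF2 genes.

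No list of markers of other cell types passed with doxorubicin. Endothelial markers were higher in 3 and lower in 2 of 15 cases (4 lower with the replicate block), with MMRN2 at 26.2 ± 5.67 against 2.72 ± 0.317 CPM and the receptor gene TEK at 6.93 ± 4.35 against 31.9 ± 2.57 CPM. Epithelial markers were higher in 3 and lower in 2 of 8 cases (4 higher adjusted over the list alone), with the keratin gene KRT17 going from 1 count over the vehicle group to 6.18 ± 0.353 CPM, a ratio of 360.4 with an exact counting interval of 64.2 to 14284, and MUC1 from 5.96 ± 0.589 to 1.66 ± 0.531 CPM. Of 6 leukocyte markers 1, ITGAM, was higher and none lower (3 higher with the replicate block). Fibroblast markers were higher in 2 and lower in 2 of 16 cases (5 and 6 with the replicate block), with the growth factor receptor gene PDGFRA at 205 ± 61.1 against 789 ± 26.5 CPM and COL13A1 at 22.0 ± 2.77 against 45.5 ± 4.06 CPM. The endothelial calls were SOX18, CLDN5 and MMRN2 higher and TEK and NOS3 lower. The epithelial calls were KRT17, CLDN7 and FOXJ1 higher and KRT18 and MUC1 lower, and the fibroblast calls APOD and SFRP2 higher and PDGFRA and COL13A1 lower. Camera adjusted p for these lists was 0.928, 0.553, 0.553 and 0.635 in that order, with medians of -0.12, 1.07, 1.48 and -0.017. The endothelial median turned to 0.11 without vehicle replicate 1 and 0.17 without doxorubicin replicate 2, the fibroblast median to 0.29 without vehicle replicate 2, 0.36 without doxorubicin replicate 1, and 0.021 and 0.023 without Nutlin-3 replicates 1 and 2, and the leukocyte median to -0.094 with only the 4 libraries compared. Left-out libraries gave medians from -0.63 to 0.17 for endothelial, 0.77 to 2.33 for epithelial, 0.95 to 3.22 for leukocyte and -0.85 to 0.36 for fibroblast markers. Genes named with doxorubicin only as members behind a count of 5 or fewer were chosen after their values were seen. The median and the mean or test of a list differed in sign for the NF-kB, matrix, integrated stress response, endothelial and fibroblast lists.

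The test behind these calls was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 9649 genes had an unadjusted p under 0.05. Of the genes called, 3299 of those higher and 2215 of those lower changed at least 2-fold, and without vehicle replicate 1 the lower calls numbered 2627. The authors' deposited table of doxorubicin against control listed 7396 genes, 4097 higher and 3299 lower, and 7007 of them were called here, all with the same sign.

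**Figure D1:**
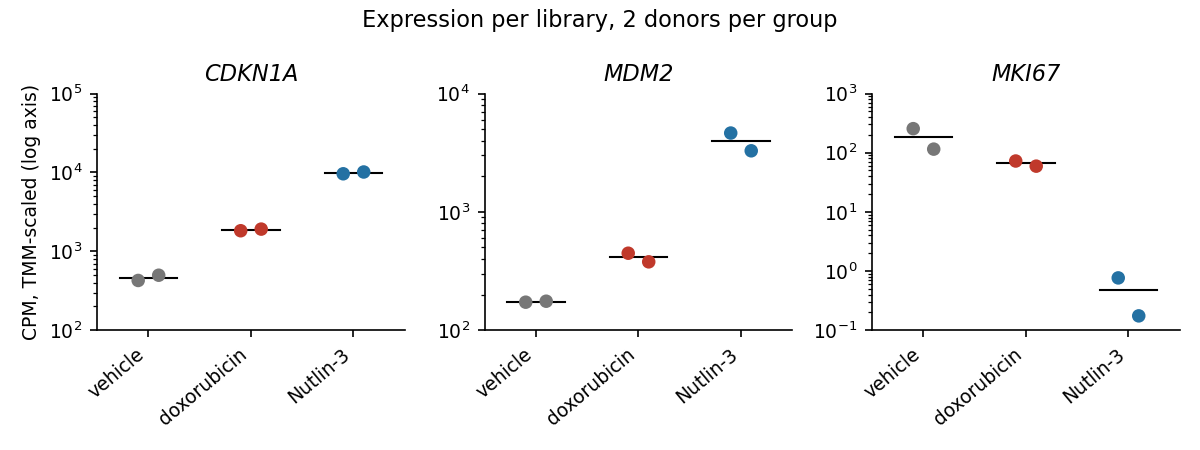
Expression of CDKN1A, MDM2 and MKI67 in each library, in CPM after TMM scaling on a log axis, by treatment. Points are the 2 donors' libraries and bars their means; CDKN1A stood at 462 CPM in vehicle, 1867 with doxorubicin and 9862 with Nutlin-3, and MKI67 at 185, 65.7 and 0.470 CPM.

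Nutlin-3 raised p53 targets and lowered cell cycle genes, with fewer genes called than under doxorubicin. Against vehicle, 555 genes were higher and 328 lower, and with the donors as a replicate block 1953 were higher and 1372 lower. CDKN1A rose 21.3-fold to 9862 ± 364 CPM (log2 fold change 4.42, SE 0.20, adjusted p = 0.00120) and MDM2 rose 22.7-fold to 3957 ± 957 CPM (log2 fold change 4.51, SE 0.24, adjusted p = 0.00166). Of 123 direct p53 targets 96 rose and none was called lower, 110 rose adjusted over the list alone, and the median log2 fold change was 1.70, or 1.67 with 9 members near 0 counts set to their bounds (camera adjusted p = 9.35e-102, adjusted p = 0.0485 with an estimated correlation). FDXR rose 11.7-fold and BTG2, an antiproliferative factor, 10.1-fold. Of the 17 apoptotic targets 12 rose and none was called lower over all genes, while 13 rose and 1 fell adjusted over the list alone (1 fell with the replicate block as well; median 2.02, camera adjusted p = 6.28e-23, adjusted p = 0.0358 with an estimated correlation). TP53I3 rose 8.94-fold to 353 ± 19.8 CPM and TNFRSF10C 12.8-fold to 28.6 ± 1.54 CPM.

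Cell cycle transcripts fell with Nutlin-3. Of 66 genes of G2/M and mitosis 63 fell over all genes and 66 adjusted over the list alone, with a median log2 fold change of -4.72 (camera adjusted p = 1.15e-98, adjusted p = 0.275 with an estimated correlation). NDC80, a kinetochore protein, fell from 21.6 ± 8.20 to 0.279 ± 0.0861 CPM and CENPF, another, from 166 ± 75.7 to 2.42 ± 0.655 CPM (log2 fold change -6.10, SE 0.42, adjusted p = 0.00283). G1/S and DNA replication genes fell in 24 and rose in 1 of 48 cases, with 41 lower adjusted over the list alone and 42 lower with the replicate block (median -1.64, camera adjusted p = 2.05e-30, adjusted p = 0.275 with an estimated correlation). The 1 higher was LIG1. RRM2, a subunit of ribonucleotide reductase, fell to 0.0179 of vehicle and UHRF1, which helps to maintain DNA methylation, to 0.0965. Recombination and Fanconi repair genes fell in 18 of 26 cases and in 22 adjusted over the list alone (median -2.66, camera adjusted p = 5.16e-26, adjusted p = 0.275 with an estimated correlation). POLQ, a DNA polymerase, fell to 0.0258 of vehicle and RAD54L, a recombination helicase, to 0.0180.

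Named by size, the largest falls were in FAM111B (chromosome 11, 59107185 to 59127410), MKI67, the proliferation marker Ki-67 (chromosome 10, 128096659 to 128126385), NEK2, a centrosomal kinase (chromosome 1, 211658657 to 211675630), and BUB1B, a spindle checkpoint kinase (chromosome 15, 40161023 to 40221136). FAM111B went from 9.07 ± 4.72 CPM to 0 counts, at least 145-fold lower with Nutlin-3 set to 3 counts over the group. MKI67 fell from 185 ± 98.8 to 0.470 ± 0.418 CPM and BUB1B from 34.6 ± 18.3 to 0.128 ± 0.119 CPM. NEK2 fell from 25.3 ± 12.8 CPM to 3 counts over the group, a ratio of 0.00248 with an exact counting interval of 0.000511 to 0.00726. Among genes with a mean log2 CPM of at least 2 over all 6 libraries, the largest rises were in PINCR, a p53-induced noncoding RNA (chromosome X, 43176994 to 43226598), NHLH2, a neuronal transcription factor (chromosome 1, 115836377 to 115843917), ABCA12, a lipid transporter on the p53 list (chromosome 2, 214931542 to 215138428), and SCN4B, a sodium channel subunit (chromosome 11, 118133377 to 118152888). PINCR, NHLH2 and SCN4B had 0 counts in vehicle and were at least 57.2-fold, 23.0-fold and 18.4-fold higher, at 2.96 ± 0.391, 1.18 ± 0.130 and 0.947 ± 0.104 CPM. ABCA12 had 1 count in vehicle and 4.62 ± 1.04 CPM with Nutlin-3, a ratio of 269 with an exact counting interval of 47.8 to 10688. These 4 met that limit through doxorubicin levels of 14.3, 16.6, 17.2 and 45.7 CPM for PINCR, NHLH2, ABCA12 and SCN4B, so genes that Nutlin-3 alone raised to such low levels were not ranked. Adjusted p ranged from 0.00278 for ABCA12 to 0.0334 for NHLH2 among these 8 genes. NHLH2, SCN4B and NEK2 lost their call without Nutlin-3 replicate 1 (adjusted p = 0.130, 0.0785 and 0.0606) and without replicate 2 (0.116, 0.0721 and 0.0720), as did RRM2, UHRF1, POLQ and RAD54L (adjusted p from 0.0544 to 0.0873). Without vehicle replicate 1 NHLH2 and SCN4B did not pass (adjusted p = 0.118 and 0.0576), nor NHLH2 without vehicle replicate 2 (adjusted p = 0.0761). With limma-voom on all libraries NHLH2, SCN4B, NEK2, POLQ and RAD54L did not pass (adjusted p = 0.0925, 0.0515, 0.0794, 0.0546 and 0.0501).

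A further 8 lists passed upward with Nutlin-3, with 9 or fewer of their members called in each. Sterol synthesis genes rose in 9 of 30 cases, in 18 with 1 lower adjusted over the list alone and in 23 with 1 lower under the replicate block (median 0.79, camera adjusted p = 5.99e-10, adjusted p = 0.275 with an estimated correlation). FADS1, a fatty acid desaturase, rose 3.50-fold and FDPS, farnesyl diphosphate synthase, 1.85-fold. Of 33 NF-kB and inflammatory factors 2 rose, LIF and BIRC3 (4 higher and 1 lower adjusted over the list alone, 19 and 1 with the replicate block; median 0.82, camera adjusted p = 3.26e-05, adjusted p = 0.491 with an estimated correlation). In the integrated stress response 2 of 28 rose, SESN2 and NUPR1, both also on the p53 list (8 adjusted over the list alone, 18 with the replicate block; median 0.60, camera adjusted p = 2.49e-05, adjusted p = 0.491 with an estimated correlation). NRF2 targets rose in 6 of 23 cases (8 adjusted over the list alone, 9 with the replicate block; median 0.37, camera adjusted p = 0.000109, adjusted p = 0.275 with an estimated correlation), with OSGIN1 up 2.38-fold and SRXN1, sulfiredoxin, up 2.52-fold. Immediate early genes rose in 5 of 26 cases (7 with 1 lower adjusted over the list alone, 9 with 1 lower under the replicate block; median 0.37, camera adjusted p = 0.000247, adjusted p = 0.467 with an estimated correlation), namely KLF4, NR4A1, NR4A2, NR4A3 and BTG2. NR4A2, a nuclear receptor, rose 4.69-fold. Histone genes rose in 3 of 34 cases (8 with 1 lower adjusted over the list alone, 18 with 1 lower under the replicate block; median 1.15, camera adjusted p = 3.39e-05, adjusted p = 0.491 with an estimated correlation), namely HIST2H2BF, HIST2H2BE and HIST1H2BJ, with HIST1H2BJ up 7.39-fold and HIST2H2BE up 4.80-fold. Interferon response genes rose in 3 of 37 cases (4 with 1 lower adjusted over the list alone, 9 with 3 lower under the replicate block; median 0.41, camera adjusted p = 0.0132, adjusted p = 0.491 with an estimated correlation), and this list did not pass with the replicate block (adjusted p = 0.0526) or without vehicle replicate 2 (median 0.27, adjusted p = 0.0916). The 3 were ISG20, RSAD2 and TRIM22, of which TRIM22 rose 3.76-fold and ISG20 4.10-fold. Ribosomal protein genes had a median of 0.18 (camera adjusted p = 0.00855, adjusted p = 0.544 with an estimated correlation) with 1 of 74 called, RPS19, none adjusted over the list alone and 3 with the replicate block. That list no longer passed with library totals as the only scaling (median 0.0086, adjusted p = 0.286), without vehicle replicate 2 (0.15, adjusted p = 0.103) or without Nutlin-3 replicate 1 (0.14, adjusted p = 0.112). Other medians kept their call but moved by more than 1.5 times. Without Nutlin-3 replicate 1 they were 0.46 for NF-kB and inflammatory factors, 0.37 for the stress response and 0.23 for NRF2 targets, without Nutlin-3 replicate 2 0.53 for histones, and without vehicle replicate 1 0.56 for NRF2 targets. With library totals they were 0.20 for NRF2 targets, 0.21 for immediate early and 0.26 for interferon genes. Of the genes named here, HIST2H2BE, ISG20, FADS1, FDPS, OSGIN1, SRXN1 and NR4A2 lost their call without vehicle replicate 1 (log2 fold changes 2.05, 1.91, 1.68, 0.88, 1.25, 1.44 and 2.18) and without Nutlin-3 replicate 2 (2.06, 2.05, 1.505, 0.74, 1.16, 1.41 and 1.96). HIST2H2BE, ISG20, FDPS, OSGIN1 and SRXN1 also lost it without Nutlin-3 replicate 1 (2.42, 1.99, 1.00, 1.31 and 1.23), and ISG20, FDPS, OSGIN1 and SRXN1 without vehicle replicate 2 (2.16, 0.88, 1.25 and 1.23). OSGIN1 and SRXN1 did not pass with library totals either (adjusted p = 0.0529 and 0.0605), nor ISG20 with only the 4 libraries compared (adjusted p = 0.0515).

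The remaining lists did not pass with Nutlin-3. ACTA2 was the contractile gene called, at 186 ± 28.2 against 43.8 ± 4.08 CPM, of 25 measured (3 higher and 5 lower with the replicate block; median -0.057, camera adjusted p = 0.382). None of 47 matrix genes was called over all genes or over the list alone, while with the replicate block 13 were higher and the list passed (adjusted p = 9.18e-05, against 0.0739 without it, median 0.25). It passed as well without vehicle replicate 2 (median 0.63), Nutlin-3 replicate 1 (0.43), doxorubicin replicate 1 (0.25) or replicate 2 (0.24), and its median was -0.02 without vehicle replicate 1 and -0.069 without Nutlin-3 replicate 2. In the BMP and TGF-beta pathway ACVRL1, a BMP receptor and also a hypertension risk gene, was the 1 of 39 lower (10 higher and 3 lower with the replicate block; median 0.21, camera adjusted p = 0.185). Among 17 hypertension risk genes TBX4 was the 1 higher and ACVRL1 the 1 lower (5 lower with the replicate block; median -0.11, camera adjusted p = 0.330). Endothelial and fibroblast markers had no calls among 15 and 16 genes (1 higher and 2 lower, and 3 higher and 2 lower, with the replicate block), epithelial markers had KRT17 higher among 8 (1 lower with the replicate block) and leukocyte markers ITGAM higher among 6, with 2 higher and 2 lower of the latter under the replicate block and 4 and 2 adjusted over the list alone. Camera adjusted p for these was 0.337, 0.974, 0.320 and 0.298, with medians of -0.25, 0.15, -0.59 and 1.14. Without vehicle replicate 1 the endothelial and fibroblast medians turned to 0.0011 and -0.14, the latter to -0.41 without Nutlin-3 replicate 2, and the leukocyte median to -0.17 with only the 4 libraries compared. Left-out libraries gave medians from -0.13 to -0.028 for contractile, 0.20 to 0.33 for BMP and TGF-beta, -0.28 to -0.081 for hypertension risk, -0.34 to 0.0011 for endothelial, -0.41 to 0.59 for fibroblast, -0.60 to -0.10 for epithelial and 0.47 to 3.13 for leukocyte genes. Genes named with Nutlin-3 only as members behind a count of 5 or fewer, such as BIRC3, RPS19 and ITGAM, were chosen after their values were seen. The median and the mean or test differed in sign for the hypertension risk and epithelial lists.

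The number of Nutlin-3 calls moved with each library left out. With edgeR 3748 genes had an unadjusted p under 0.05, and leaving out 1 library gave 109 higher and 25 lower without Nutlin-3 replicate 1, 119 and 24 without Nutlin-3 replicate 2, 132 and 97 without vehicle replicate 1, 205 and 236 without vehicle replicate 2, and 356 and 359 higher without doxorubicin replicates 1 and 2. DESeq2 called 1151 higher and 905 lower, and with library totals as the only scaling, which moved the median of all genes by -0.16, 354 were higher and 366 lower, 49.2% higher in place of 62.9%. The authors' deposited table of Nutlin-3 against control listed 1501 genes, 811 higher and 690 lower, and 839 of them were called here, all with the same sign.

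**Figure D2:**
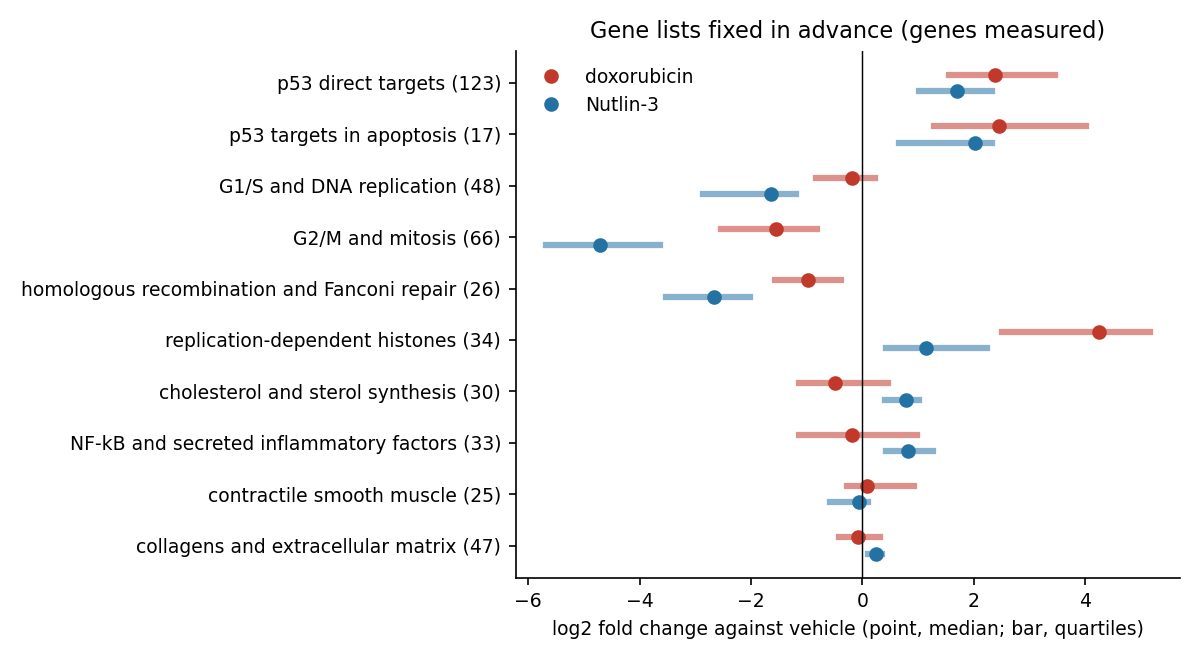
Log2 fold change against vehicle of 10 gene lists for doxorubicin and Nutlin-3. Points are medians over the measured genes (their number in parentheses) and bars run from the lower to the upper quartile; the G2/M and mitosis list lay at -1.54 with doxorubicin and -4.72 with Nutlin-3, and the histone list at 4.26 and 1.15.

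The treatments were then compared with each other, which asks where genotoxic stress and direct activation of p53 differed. Doxorubicin libraries had 3927 genes higher and 3650 lower than Nutlin-3 libraries. The highest differences were NOTO, RNASE7, a skin antimicrobial ribonuclease (chromosome 14, 21042226 to 21044234), PRR26 (chromosome 10, 649948 to 669581), CA7, a carbonic anhydrase (chromosome 16, 66844379 to 66854153), and SLC18A3, the vesicular acetylcholine transporter (chromosome 10, 49610301 to 49612720), all with 0 counts under Nutlin-3. With Nutlin-3 set to 3 counts over the group they were at least 819-fold, 630.2-fold, 536-fold, 323-fold and 295-fold higher with doxorubicin, and adjusted p lay between 0.00179 and 0.00294. Lowest relative to Nutlin-3 were C3orf80 (chromosome 3, 160225496 to 160228213), ENPP4, GBP2, KCND2, a potassium channel (chromosome 7, 120273668 to 120750331), and KCNAB1. C3orf80 stood at 0.399 ± 0.124 CPM with doxorubicin and 12.4 ± 0.294 with Nutlin-3, and KCND2 at 0.751 ± 0.566 and 16.7 ± 1.64 CPM. ENPP4, GBP2 and KCNAB1 were at 0.0400, 0.0408 and 0.0502 of their Nutlin-3 level (adjusted p = 0.0237, 0.00802 and 0.0341), and ENPP4 and KCNAB1 lost the call without either doxorubicin library (adjusted p = 0.0713 and 0.165 without replicate 1, 0.102 and 0.147 without replicate 2) or without Nutlin-3 replicate 1 (log2 differences -3.31 and -2.39), GBP2 without doxorubicin replicate 1 (-4.57, adjusted p = 0.0647). With limma-voom none of the 3 passed (adjusted p = 0.0917, 0.0621 and 0.192), while with edgeR's replicate block all did (adjusted p = 6.60e-05, 0.000131 and 0.000795).

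Cell cycle genes were higher with doxorubicin than with Nutlin-3, and p53 targets differed as well. Of the G2/M and mitosis list 55 of 66 were higher (median difference 3.18, camera adjusted p = 2.22e-17, adjusted p = 0.544 with an estimated correlation), of the G1/S list 28 of 48 with 2 lower (1.70, adjusted p = 9.44e-07, adjusted p = 0.695 with an estimated correlation) and of the repair list 14 of 26 (1.30, adjusted p = 0.000515, adjusted p = 0.695 with an estimated correlation). Among p53 targets 77 were higher and 9 lower with doxorubicin (15 lower with the replicate block; median 0.73, adjusted p = 5.84e-09, adjusted p = 0.539 with an estimated correlation), with CDKN1A at 0.189 of its Nutlin-3 level (adjusted p = 0.00146) and FDXR at 314 ± 11.1 against 175 ± 8.86 CPM. Of the apoptotic targets 10 were higher and 2 lower (0.79, adjusted p = 0.000673, adjusted p = 0.539 with an estimated correlation), and of histones 23 were higher (2.59, adjusted p = 2.02e-10, adjusted p = 0.539 with an estimated correlation). Adjusted over each list alone, these counts were 58 higher for G2/M, 31 and 2 for G1/S, 14 for repair, 81 and 11 for p53 targets, 10 and 2 for apoptotic targets and 24 for histones. The members lower with doxorubicin were MCM3 and SLBP of the G1/S list and BAX and TNFRSF10D of the apoptotic list, named after their values were seen.

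Lists that were lower with doxorubicin than with Nutlin-3 were sterol synthesis (19 lower and 5 higher, median -1.14, camera adjusted p = 6.77e-06), ribosomal proteins (42 and 2, -0.42, 1.41e-05), NRF2 targets (9 and 2, -0.74, 0.00844), BMP and TGF-beta genes (16 and 6, -0.52, 0.00844) and the integrated stress response (12 and 5, -0.68, 0.0473). With an estimated correlation the adjusted p was 0.539 for the first 4 and 0.800 for the last. Higher and lower counts adjusted over the list alone were 5 and 20, 2 and 48, 2 and 9, 6 and 16, and 5 and 12 in the same order. With the replicate block 6 ribosomal protein genes were higher, and with library totals that median was -0.27. The integrated stress response did not pass with the replicate block (adjusted p = 0.0710), without doxorubicin replicate 2 (median -0.41, adjusted p = 0.419) or without Nutlin-3 replicate 1 (-0.34, adjusted p = 0.127). NF-kB and inflammatory factors (11 lower, 4 higher, median -0.73) missed the threshold at 0.0596 and passed with the replicate block at 0.00746, where 17 were lower and 8 higher. It also passed without vehicle replicate 1 (median -0.74), vehicle replicate 2 (-0.74) or Nutlin-3 replicate 2 (-1.07). The matrix list passed without doxorubicin replicate 2 (-0.65, adjusted p = 0.0283) or Nutlin-3 replicate 1 (-0.49, adjusted p = 0.00988), and the epithelial list without Nutlin-3 replicate 1 (1.66, adjusted p = 0.0365). Members higher with doxorubicin were PMVK, TM7SF2, HSD17B7, EBP and FADS1 in sterol synthesis, RPS27 and RPL9 among ribosomal proteins, GCLC and AKR1B10 among NRF2 targets, DDIT3, SLC3A2, CEBPB, ATF3 and PPP1R15A in the stress response and VCAM1, MMP3, LIF and TNFAIP2 among inflammatory factors. With all libraries and the main settings no other list passed, namely interferon (9 higher, 8 lower, median 0.18), contractile (10, 3, 0.21), matrix (1, 8, -0.13; 7 and 21 with the replicate block), hypertension risk (2, 6, -0.38), immediate early (8, 5, 0.077), endothelial (3, 1, 0.12), epithelial (2, 1, 1.10), leukocyte (1, 1, -0.014) and fibroblast genes (1, 3, 0.081), with adjusted p from 0.148 to 0.846. With no filter on low counts the matrix (median -0.18, camera adjusted p = 0.0268) and epithelial lists (2.05, 0.0409) passed. The epithelial list also passed with fry (adjusted p = 0.0125). With the replicate block 14 interferon genes, 2 leukocyte, 5 epithelial and 2 fibroblast markers were higher, and 8 immediate early genes and 2 endothelial markers lower. Without doxorubicin replicate 1 the matrix and endothelial medians turned to 0.039 and -0.35, without doxorubicin replicate 2 the leukocyte and fibroblast medians to 0.39 and -0.85, and without Nutlin-3 replicate 1 the same 2 to 0.15 and -0.47. Without Nutlin-3 replicate 2 the matrix, endothelial and leukocyte medians turned to 0.16, -0.40 and 0.27. Left-out libraries gave medians from -1.07 to -0.40 for NF-kB, 0.059 to 0.38 for interferon, 0.19 to 0.79 for contractile, -0.65 to 0.16 for matrix, -0.49 to -0.20 for hypertension risk and 0.03 to 0.14 for immediate early genes. For markers they ran from -0.40 to 0.49 (endothelial), 0.82 to 1.66 (epithelial), -0.68 to 0.39 (leukocyte) and -0.85 to 0.74 (fibroblast). Over all genes, CAV1 and EIF2AK4 among hypertension risk genes, COL12A1 in the matrix list, SOX18, CLDN5 and MMRN2 among endothelial, CLDN7 and FOXJ1 among epithelial, CORO1A among leukocyte and SFRP2 among fibroblast genes were higher. Lower were TPM1, LPP and PPP1R12B of the contractile, KLF2, NR4A2, NR4A3, CYR61 and CTGF of the immediate early, NOS3 of the endothelial, MUC1 of the epithelial, CD68 of the leukocyte and PDGFRA, COL13A1 and FGF7 of the fibroblast list. These members were named after their values were seen. The median and the mean or test differed in sign for the leukocyte and fibroblast lists. Over all lists, 7 passed with doxorubicin, 13 with Nutlin-3 and 11 between the treatments, and with an estimated correlation 0, 2 and 0 did, the 2 being the p53 lists with Nutlin-3.

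Doxorubicin and Nutlin-3 changed 665 genes in the same direction, 475 higher and 190 lower, where independent lists of these sizes would share 155.5 and 81.4. Another 17 genes were higher with doxorubicin and lower with Nutlin-3, and 18 the reverse. Of these, the 4 with the smallest p between the treatments were RAB7B, a small GTPase (chromosome 1, 205976740 to 206003461), PAPPA2, a protease of insulin-like growth factor binding proteins (chromosome 1, 176463171 to 176845605), MVD, an enzyme of sterol synthesis (chromosome 16, 88651935 to 88663161), and DTWD1 (chromosome 15, 49620980 to 49656232). RAB7B stood at 7.97 ± 0.167 CPM in vehicle, 46.6 ± 2.61 with doxorubicin and 3.80 ± 0.498 with Nutlin-3. PAPPA2 stood at 47.9 ± 0.679, 22.5 ± 1.38 and 107 ± 15.3 CPM, MVD at 38.9 ± 4.16, 13.1 ± 0.0490 and 74.5 ± 15.9 CPM, and DTWD1 at 36.7 ± 0.670, 15.7 ± 0.882 and 63.4 ± 10.2 CPM in the same order. When all 6 libraries were simulated without any effect, from the fit without the donor block, the shared vehicle libraries gave a mean of 0.11 shared higher and 0.03 shared lower calls. Few genes can be called without an effect, so these means say nothing about sharing between lists of the sizes found. The covariance of the fold changes was 1.17 against 0.153 in the simulations, a difference of 1.01, while the correlation was 0.530 against 0.477 (highest of 100 simulations 0.508) and the same-sign share, at 64.1% against 66.3%, lay below the simulated mean. The 2 vehicle libraries cannot be split into separate sets of 2, and the simulation did not carry the donor differences, so part of the excess over independent lists may come from the shared controls. With the replicate block 2163 genes were called in the same direction, with DESeq2 1374. Leaving out a library gave 134 and 140 such genes without Nutlin-3 replicates 1 and 2, 171 and 348 without vehicle replicates 1 and 2, and 434 without doxorubicin replicate 2.

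**Figure D3:**
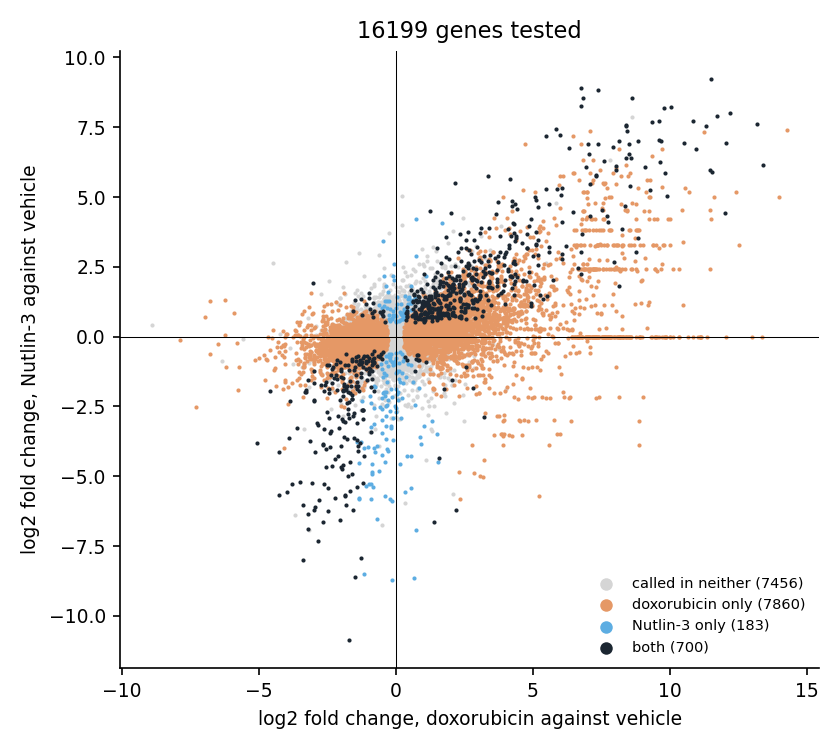
Log2 fold change with doxorubicin (x axis) and with Nutlin-3 (y axis) against the same vehicle libraries, 1 point for each of 16199 genes tested, coloured by call at an adjusted p under 0.05. Both treatments called 700 genes, doxorubicin alone 7860 and Nutlin-3 alone 183, and the horizontal stripes of points are genes with few or 0 counts in vehicle and Nutlin-3.

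Limits on single genes apply throughout. The contrast of doxorubicin and Nutlin-3 had 8956 genes with an unadjusted p under 0.05, and with library totals as the only scaling, which moved the median of all genes by 0.16, 62.1% of its calls were higher in place of 51.8%. Its counts were 2438 higher and 2130 lower without doxorubicin replicate 1, 2169 and 1803 without Nutlin-3 replicate 1, and 2187 and 2010 without Nutlin-3 replicate 2. Whether reads were assigned by strand was not given in the sources used here, so the values of CRTAC1, KCNAB1, ABCA12, RNASE7, PRR26, CA7, C3orf80, KCND2, RAD54L, PLK1, GINS4, TP53I3, LIF, IL6, ACTA2, ENG, VLDLR, FADS1, FDPS and RPL9, which lie across from a gene on the opposite strand, are uncertain to that extent. GBP2, BUB1B, RRM2, SLC18A3, BRCA1, TM7SF2, OSGIN1, SRXN1, MUC1 and PDGFRA overlap a gene on their own strand, and MDM2, TRIM22, SMTN, THBS1, ATP13A3, GCLC and MMRN2 overlap genes on both. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.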

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

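The test of S phase genes against histones was chosen only after the result was seen, and so were the patterns weighed here. The 5 lists below stand out because the test between the treatments passed and their medians against vehicle had opposite signs. Against vehicle itself with the main settings, BMP and TGF-beta genes passed with neither treatment, and sterol, stress response and NRF2 genes did not pass with doxorubicin (adjusted p = 0.190, 0.989 and 0.635), so opposite movement was not shown for these 4. With no filter on low counts BMP (median -0.38) and sterol genes (-0.54) passed downward with doxorubicin (camera adjusted p = 0.0477 for both). Opposite movement of sterol genes thus depended on the filter. For ribosomal proteins opposite movement was not firm, as their rise with Nutlin-3 did not pass with library totals (median 0.0086, adjusted p = 0.286) or with fry (0.0560). It did not pass without vehicle replicate 2 or Nutlin-3 replicate 1 either. Against vehicle with an estimated correlation that list had an adjusted p of 0.889 with doxorubicin and 0.544 with Nutlin-3. The doxorubicin median turned positive without doxorubicin replicate 2 for the stress response (0.052) and without vehicle replicate 1 for NRF2 targets (0.073). The median log2 difference of doxorubicin minus Nutlin-3 was -0.52 for the BMP and TGF-beta pathway (adjusted p = 0.00844), -1.14 for cholesterol and sterol synthesis (6.77e-06), -0.68 for the integrated stress response (0.0473), -0.74 for NRF2 targets (0.00844) and -0.42 for ribosomal proteins (1.41e-05). With an estimated correlation these adjusted p were 0.539, 0.539, 0.800, 0.539 and 0.539. The stress response did not pass without doxorubicin replicate 2 (median -0.41) or Nutlin-3 replicate 1 (-0.34). Among single genes called in opposite directions against vehicle, the log2 difference was 3.62 for RAB7B (adjusted p = 0.000952), -2.25 for PAPPA2 (0.00120), -2.50 for MVD (0.00146) and -2.02 for DTWD1 (0.00146).

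Replication-dependent histone transcripts rose with doxorubicin, with a lower quartile of 2.51 on the log2 scale. Had more cells in S phase raised G1/S and replication genes about as much, their upper quartile would lie near the histones, but it was 0.23. That list also fell with Nutlin-3 (median -1.64), so p53 activation may lower it whatever the share of cells in S phase. The test therefore cannot decide on S phase. Bias toward short genes is argued against by 486 other short protein-coding genes, whose median was 0.28. Lists matched on vehicle level had a median of 1.36, so part of the histone median of 4.26 may go with a low level. Of 10000 such lists 0 reached it (highest 3.12). Those lists drew genes independently, while histone genes are near-identical copies that may move together, so the draws may understate the spread. With an estimated correlation the histone list had a camera adjusted p of 0.669. The draws therefore cannot decide whether a low level is the whole cause. The summed CPM of 64 copies rose from 80.5 and 127.1 to 802.1 and 1249.7, which argues against reads moving among these copies, and whether libraries were poly(A)-selected or depleted of ribosomal RNA was not given in the sources used here. A change in the 3' end processing of these transcripts may account for the rise, a hypothesis these tables leave untested.

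Longer genes fell more with doxorubicin, with a Spearman correlation of gene span and fold change across 10449 genes of -0.190, against 0.023 with Nutlin-3 (genes are not independent replicates). From the shortest to the longest of 8 bins the median log2 fold change went from -0.011 to -0.63 and the share called lower from 24.9% to 51.8%. The partial correlation was -0.166 with exonic length held constant (bootstrap interval -0.184 to -0.147) and -0.187 with vehicle level held constant (-0.206 to -0.169), and the weaker of the 2 replicate numbers gave -0.185 (-0.203 to -0.166), which argues against exonic length, expression level or 1 aberrant library as the whole cause. Whether intronic reads were counted stays open. Impaired elongation on damaged DNA may account for it, as a hypothesis that was not tested.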

How the results depend on the processing

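None of the alternatives here was added after the values were seen. Of 93 results of genes picked by the naming rule under 13 alternatives each (1209 in all), 1143 kept direction and side of the threshold, 66 lost the call, none gained one and none reversed. All alternatives kept the call of 74, and 19 lost it under any, with adjusted p from 0.0501 to 0.192; the replicate block changed none of them. Of 63 list results, 21 were the same under all alternatives that keep every library. Where a left-out library, another tool or scaling changed a call, the cause was not tested. A left-out library also left its group with 1 donor against 2 in the others, so such shifts mix donor and treatment. They can also come from other list members passing the filter, which was rerun each time. Values below are gene counts or median log2 fold changes of the lists. With a change of at least 2-fold lower counts were genes lower 2215 (doxorubicin), genes lower 1853 (between treatments). With library totals alone lower counts were genes higher 354 (Nutlin-3). Lists that lost the call were ribosomal 0.0086 (Nutlin-3). Lists that gained it were NF-kB -0.60 (between treatments). Lists not called whose median changed sign were fibroblast -0.029 (Nutlin-3), matrix 0.022, leukocyte 0.15 (between treatments). With DESeq2 higher counts were genes higher 1151, genes lower 905 (Nutlin-3), same-direction genes 1374. With the replicate block lists that lost the call were interferon 0.34 (Nutlin-3), stress response -0.69 (between treatments). Higher counts were genes higher 1953, genes lower 1372 (Nutlin-3), same-direction genes 2163. Lists that gained it were matrix 0.27 (Nutlin-3), NF-kB -0.69 (between treatments). With RLE scaling in place of TMM lists that gained it were NF-kB -0.68 (between treatments). Lists not called whose median changed sign were fibroblast 0.012 (doxorubicin), leukocyte 0.039 (between treatments). With limma-voom lists that lost the call were immediate early 0.80 (doxorubicin), stress response -0.61 (between treatments). Lists that gained it were matrix 0.27 (Nutlin-3). With no filter on low counts lists that lost the call were immediate early 0.75 (doxorubicin). Lists that gained it were BMP -0.38, sterol -0.54 (doxorubicin), matrix 0.25 (Nutlin-3), NF-kB -0.75, matrix -0.18, epithelial 2.05 (between treatments). Lists not called whose median changed sign were leukocyte 0.33 (between treatments). With only the 4 libraries compared lists that gained it were matrix 0.24 (Nutlin-3), NF-kB -0.74 (between treatments). Lists not called whose median changed sign were leukocyte -0.094 (doxorubicin), leukocyte -0.17 (Nutlin-3), fibroblast -0.034 (between treatments). With an estimated correlation lists that lost the call were p53 targets 2.38, apoptotic targets 2.45, G2/M -1.54, repair -0.98, histones 4.26, immediate early 0.79, ribosomal -0.27 (doxorubicin), G1/S -1.64, G2/M -4.72, repair -2.66, histones 1.15, interferon 0.41, NF-kB 0.82, sterol 0.79, stress response 0.60, NRF2 0.37, immediate early 0.37, ribosomal 0.18 (Nutlin-3), p53 targets 0.73, apoptotic targets 0.79, G1/S 1.70, G2/M 3.18, repair 1.30, histones 2.59, BMP -0.52, sterol -1.14, stress response -0.68, NRF2 -0.74, ribosomal -0.42 (between treatments). With fry lists that lost the call were G2/M -1.54, repair -0.98, immediate early 0.79 (doxorubicin), G1/S -1.64, G2/M -4.72, repair -2.66, histones 1.15, interferon 0.41, NF-kB 0.82, sterol 0.79, stress response 0.60, NRF2 0.37, immediate early 0.37, ribosomal 0.18 (Nutlin-3), G1/S 1.70, G2/M 3.18, repair 1.30, stress response -0.68, NRF2 -0.74 (between treatments). Lists that gained it were epithelial 1.07 (doxorubicin), epithelial 1.10 (between treatments). Leaving out 1 library ranged, for doxorubicin, over genes lower 2627 to 3743, G1/S -0.58 to 0.29, repair -1.43 to -0.45, NF-kB -0.34 to 0.31, contractile -0.011 to 0.53, sterol -0.62 to -0.36, NRF2 -0.33 to 0.073, immediate early 0.67 to 0.80, endothelial -0.63 to 0.17, matrix -0.39 to 0.41, fibroblast -0.85 to 0.36, stress response -0.54 to 0.052. Leaving out 1 library ranged, for Nutlin-3, over genes higher 109 to 359, genes lower 24 to 247, matrix -0.069 to 0.63, endothelial -0.34 to 0.0011, fibroblast -0.41 to 0.59, interferon 0.27 to 0.46, ribosomal 0.14 to 0.19. Leaving out 1 library ranged, between treatments, over genes higher 2169 to 3739, genes lower 1803 to 3411, NF-kB -1.07 to -0.40, matrix -0.65 to 0.16, endothelial -0.40 to 0.49, stress response -0.92 to -0.34, leukocyte -0.68 to 0.39, fibroblast -0.85 to 0.74, epithelial 0.82 to 1.66. Leaving out 1 library ranged, over same-direction genes 134 to 450. Genes at 0 or a few counts give bounds only, and at this depth 3 counts over a group set that floor.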

Other observations

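Gene families named here, the test of each, and the tests of background and neighbouring genes were chosen only after the values were seen. Of 19268 genes under 0.1 CPM in vehicle, 101 had a mean above 5 CPM with doxorubicin, 73 of them in both libraries, and 1 with Nutlin-3. In reverse, 0 genes went from above 5 CPM in vehicle to under 0.1 CPM with doxorubicin and 3 with Nutlin-3. The limit of 5 CPM does not mark the 101 as particular to doxorubicin. Among them at least ABCA12, PINCR, KRT17, POU3F1, NHLH2 and SCN4B were called higher with Nutlin-3 too. They stood at 4.62, 2.96, 2.81, 1.57, 1.18 and 0.947 CPM, while NOTO and RNASE7 stood at 0. The 101 included the p53 targets GLS2 and ABCA12 and the p53-induced PINCR, and how many more are p53 targets was not counted. They also included the lineage factors GATA3, POU4F1, LHX3 and FOXD3, the signalling protein NODAL, and the late cornified envelope genes LCE1B, LCE1C and LCE1F of the skin barrier. Homeobox genes, which set body pattern, were 9 of 110 silent members against 83 of 5780 silent protein-coding genes (8.18% against 1.44%; Fisher's exact test, two-sided, p = 2.39e-05, adjusted p = 0.000239 over 10 families). Late cornified envelope genes were 3 of 18 (exact p = 0.00199, adjusted p = 0.00603) and forkhead genes 1 of 23 (adjusted p = 0.405). LCE1F, LCE1C and LCE1B lie together on chromosome 1, from 152776372 to 152813109. The exact tests of families took genes as independent, so members that move together or share reads may make these p too small. Olfactory receptors gave 0 of 353, fewer than the background (exact p = 0.00936, adjusted p = 0.0187), keratin-associated proteins 0 of 94 (adjusted p = 0.808), WNT ligands 0 of 9 and ZNF genes 0 of 40 (adjusted p = 1 for both).

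Among genes lower with doxorubicin, 8 of 11 SR splicing factors fell and 1 rose, against 27.6% of 13680 genes (Fisher's exact test, adjusted p = 0.00603; median log2 fold change -0.65). Guanylate-binding proteins, interferon-inducible GTPases, fell in 4 of 5 cases (exact, adjusted p = 0.0378; median -3.39). Kinesins, microtubule motors, fell in 18 of 34 cases and rose in 4 (exact, adjusted p = 0.00603; median -1.10). With Nutlin-3, where 2.35% of the 13680 genes were lower, 13 of the 34 kinesins (Fisher's exact test, adjusted p = 9.55e-13 over 3 families), 2 of the 11 SR factors (exact, adjusted p = 0.0396) and 1 of the 5 guanylate-binding proteins (exact, adjusted p = 0.112) were lower. PTGIS, prostacyclin synthase, went from 1439 ± 468 to 84.8 ± 39.3 CPM with doxorubicin (n = 2; edgeR adjusted p = 0.00535) and stood at 1141 CPM with Nutlin-3. POLR2A, the largest subunit of RNA polymerase II, went from 281 to 1091 CPM.

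The genes nearly silent in vehicle were weighed against technical explanations. Selection of genes by a low vehicle level would give a like number in reverse, and the reverse count with doxorubicin was 0. Evenly spread background, such as genomic DNA, would follow length, but of the silent genes at least as long as the median of the 101 only 0.824% by span and 1.85% by exonic length stood above 5 CPM with doxorubicin. A gene of either strand above 5 CPM overlapped or lay within 10000 bases of 39 of the 101, or 38.6% (exact 95% interval 29.1% to 48.8%). Of these 39, 29, or 74.4% (57.9% to 87.0%), stood below their highest neighbour, so reads from a neighbour stay open for these. The other 62 had no such neighbour, which argues only against reads from genes above 5 CPM within 10000 bases. Reads from farther off or from weaker genes were not tested. The share with such a neighbour among all silent genes was not computed. Loss of gene silencing with doxorubicin may be a source for some of those 62, which is a hypothesis that these data do not test. Activation of p53 as a source was not weighed here.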
